A study of Mus musculus with 8 samples.

How the data were processed

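The series holds 8 acetyl-H4 ChIP-seq libraries from bone-marrow-derived macrophages of C57BL/6 mice: untreated, PAM3, 25HC, and 25HC then PAM3. Each of the 4 groups holds 1 library from mouse A and 1 from mouse B, per the labels. PAM3 stands for PAM3CSK4 and 25HC for 25-hydroxycholesterol. The label for stimulation time gives no unit and reads 0 in every library without PAM3 and 18 in every library with it. An effect of PAM3 therefore cannot be told apart from one of that time.

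Reads were aligned with GSNAP to GRCm38 (mm10) and broad peaks were called with MACS2 2.1.0, per the submitters' processing notes. The deposited files are broadPeak lists, 1 per library, with a start and an end for each peak. Each list also carries the authors' score per peak, which equalled 10 times the −log10 q without its decimals in 99.994% to 100.0% of the peaks of a library. The deposited enrichment column is the authors' fold ratio over the local background of the peak caller, and the deposited −log10 p and −log10 q columns are the authors' means over each peak. The per-peak values were used as deposited. Control libraries, read filters and calling thresholds are not given in the sources used here. The lists hold no read counts, so the read depth is unknown and no counting interval was computed.

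The measure was called length: the bp of the deposited peaks of a library that lie in a gene's window, the gene body with 5 kb on either side, on the autosomes, X and Y. Gene bodies came from a RefSeq table on GRCm38.p6 without strand. Of 21883 protein-coding genes, the 14586 with a mean called length of at least 500 bp over the 8 libraries were tested. Log2 values are log2 of called bp plus 500 bp, with the median of each library subtracted, so they understate changes of genes with little called length. Where a group is at 0 the 500 bp sets the size of a log2 change. Called lengths are then given in its place, except in the figure of cytokine genes, where Il12a is at 0 with 25HC, and for changes of sign under alternatives. List medians include such genes. Libraries of a group that are both at 0 also show almost no spread, so the adjusted p of such a gene can be too small. Without that subtraction, the median gene differed between groups by −0.05 to 0.01 on the log2 scale. Windows of 10191 of the 14586 genes (69.9%) overlap another gene's window, so neighbours can share a peak.

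One model over the 4 groups was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust settings). It has 4 residual degrees of freedom, or 3 with the mouse as a block, and a median prior of 1.77 degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 are said to have risen or fallen. The 7 contrasts were PAM3 against untreated, 25HC then PAM3 against 25HC, 25HC against untreated, 25HC then PAM3 against PAM3, the difference of the PAM3 response with and without 25HC, and the average effects of PAM3 and of 25HC over 4 libraries against 4. In data simulated for PAM3 against untreated on the 14586 genes, 13 of 100 genes changed by log2 1 and 68 of 100 changed by log2 2 were called, none in the wrong direction, with 12 false calls. Those 12 made up a larger share of the simulated calls than the threshold of 0.05 aims at.

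Libraries with the same letter come from the same mouse, per the labels. Their deviations from the group means correlated by −0.0171 to 0.0304 between groups. The fit without the block is the one reported, and values with the mouse as a block are given in each comparison whose calls they end.

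The groups, contrasts, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The rule took, per contrast, the 10 largest rises and the 10 largest falls among genes under adjusted p 0.05 with the same sign in both mice, or the 3 smallest p per direction where none passed. It added 22 fixed genes, up to 4 members of each list by smallest p, and the 3 longest runs of gained and of lost bins. Predicted genes and olfactory and vomeronasal receptors were skipped. A few genes that the rule picked are not reported here. The 20 lists were cytokines and chemokines, inflammatory effectors and NF-κB feedback, immediate-early and AP-1 genes, interferon-stimulated genes, cholesterol synthesis and SREBP targets, LXR targets, the integrated stress response, glycolysis and hypoxia, NRF2 and metallothionein genes, macrophage identity, alternative activation, antigen presentation, proliferation, neutrophil, lymphocyte, dendritic cell, fibroblast and endothelial, and erythroid and megakaryocyte markers, housekeeping genes, and genes silent in macrophages. Lists were tested against all other genes with camera in limma at a preset correlation of 0.01, and again with the correlation estimated from the residuals.

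For regions, the genome was divided into 1 kb bins, and a bin was called where peaks covered at least 50% of it. A bin was gained or lost where both libraries of one group had it and neither of the other did, or all 4 against none for the average effects. The same counts were taken for other splits of the same libraries. Overlap of peak sets is the shared bp of a pair of libraries over the bp in either.

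The alternatives were 20 kb flanks, a pseudocount of 2000 bp, no filter on called length, no subtraction of the median, quantile normalisation, only peaks with a deposited −log10 q of at least 5, the same number of peaks per library, the mouse as a block, 2 kb bins, a bin called at an overlap of 1 bp, and leaving out each library in turn. Gene bodies without flanks and the same covered length per library were added after seeing the data. The deposited −log10 p agreed poorly between mice away from chromosome starts, as given under the other observations. The −log10 q minimum and the same number of peaks may thus choose peaks partly at random. They do not decide whether strong peaks changed. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 computed the rest.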

Results

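Acetylation of histone H4, a mark of active promoters and enhancers, was mapped in bone-marrow-derived macrophages of C57BL/6 mice. The cells were left untreated, given PAM3, a synthetic bacterial lipopeptide sensed by Toll-like receptors, given 25HC, an oxysterol that activated macrophages make from cholesterol, or given 25HC and then PAM3. Each of the 4 groups held 2 libraries, 1 each from mouse A and mouse B. The deposited lists held 48446 to 54552 peaks per library, with median peak lengths of 1028 to 1227 bp. They covered between 56.6 Mb (PAM3, mouse A) and 72.4 Mb (PAM3, mouse B). Covered length was 65.5 ± 7.01 Mb (SD, n = 4) with PAM3 and 64.6 ± 3.53 Mb (SD, n = 4) without, a difference of 0.954 Mb (two-sided exact permutation test, p = 0.829). It was 64.4 ± 4.02 Mb (SD, n = 4) with 25HC and 65.7 ± 6.70 Mb (SD, n = 4) without, a difference of −1.28 Mb (two-sided exact permutation test, p = 0.743). Both tests permuted the libraries freely, although the same mice gave libraries to every group.

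Peak sets sorted by PAM3 more than by 25HC, clearly so only for 25HC in cells without PAM3. The 4 pairs of libraries from the same group shared a median of 0.653 of their covered bp (0.588 to 0.670). The 8 pairs alike in PAM3 and differing in 25HC shared 0.601 (0.530 to 0.666), and the 16 pairs differing in PAM3 shared 0.510 (0.479 to 0.544). Of the 8 pairs, those without PAM3 shared 0.645 to 0.666. Those with PAM3 shared 0.530 to 0.556, which overlaps the pairs differing in PAM3. Peaks were called in 117757 bins of 1 kb in at least 1 library, and 25550 of these bins were called in all 8.

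PAM3 against untreated cells asks how the lipopeptide, together with its stimulation time, changes H4 acetylation in macrophages without added oxysterol. With PAM3, acetylation rose over Lcn2, which encodes the iron-starving protein lipocalin, over Camp, the cathelicidin precursor, the formyl peptide receptor genes Fpr1 and Fpr2, the acute-phase gene Saa2, and the scavenger receptor gene Marco. It also rose over Adgre1, a surface marker of mature macrophages. Acetylation fell over Tlr4, the lipopolysaccharide receptor gene, over Ciita, the master regulator of class II antigen presentation, and over Cd163, a scavenger receptor for haemoglobin. It fell as well over Siglech and Clec9a, lectin genes of dendritic cells. The window of Clec9a overlaps that of Clec1a, another lectin gene that fell. The calls of Ciita, Cd163 and Clec9a ended with the mouse as a block. Of 14586 genes tested, 562 passed, with 275 rising and 287 falling. This balance turned with the group that lost a library. Most calls rose without either untreated library, and most fell without either PAM3 library. Calls thus leaned towards shorter acetylation in the group left with a single library, whichever of its libraries was left out.

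Lcn2 (chromosome 2, 32384637 to 32387739) went from 1342 ± 6.4 to 3888 ± 308 bp of called length (SD, n = 2 each), a log2 change of 1.30 with a standard error of 0.10 (adjusted p = 0.0117). Adgre1 (chromosome 17, 57358581 to 57483529) went from 3629 ± 540 to 19530 ± 3406 bp (SD, n = 2 each; log2 change 2.32, adjusted p = 0.011). Fpr1 rose by 1.17 and Fpr2 by 1.83 on the log2 scale (adjusted p = 0.0117 and 0.0121), and their windows overlap. Siglech fell from 4687 ± 716 to 327 ± 2.80 bp (SD, n = 2 each; adjusted p = 0.00996). Tlr4 (chromosome 4, 66827551 to 66846581) fell from 6197 ± 122 to 2604 ± 480 bp (SD, n = 2 each), a log2 change of −1.07 (adjusted p = 0.0159). The peak at the left end of Tlr4 was missing from both PAM3 libraries and present in all others. Several windows had no peak in untreated cells. With PAM3, Nhs, an actin-remodelling gene on chromosome X (161833290 to 162159441), reached 6587 ± 814 bp (SD, n = 2; adjusted p = 0.00392). Saa2 reached 3605 ± 1824 bp (SD, n = 2; adjusted p = 0.0127), Marco 2847 ± 95.5 bp (SD, n = 2; adjusted p = 0.0159) and Camp 1612 ± 133 bp (SD, n = 2; adjusted p = 0.0159). The procollagen protease gene Bmp1 reached 3293 bp (adjusted p = 0.011) and the zinc finger gene Zfp811 2995 bp (adjusted p = 0.0117). Drosha, which starts microRNA processing, and the transporter gene Abca6 went from 4964 and 3535 bp to 0 with PAM3 (adjusted p = 0.0117 for each). Drosha was at 0 in the PAM3 group alone, as was Ms4a13 among the genes that follow, and gene windows called in 7 libraries were at 0 in single ones 651 times over the 8 libraries.

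**Figure D1:**
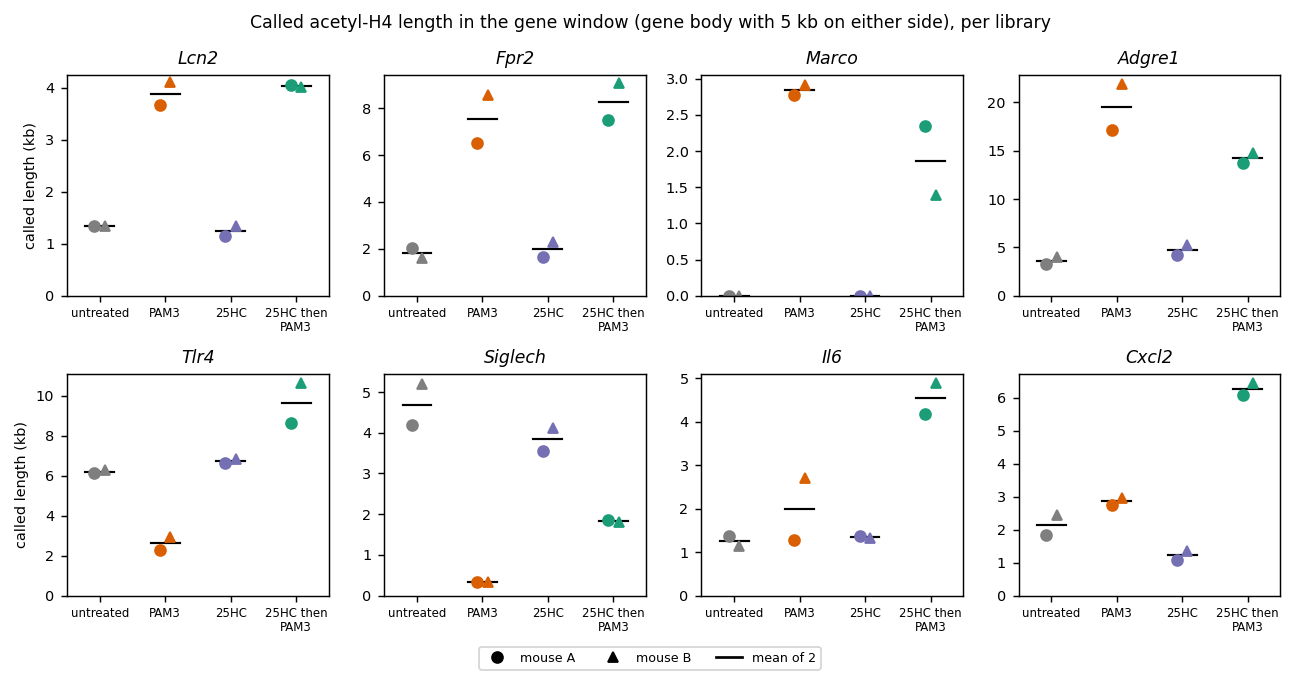
Called acetyl-H4 length in kb over the windows of 8 genes, with circles for mouse A, triangles for mouse B and lines for the mean of each group. Lcn2, Fpr2, Marco and Adgre1 lie higher in both PAM3 groups, Siglech lies lower there, Tlr4 has its lowest values with PAM3 alone, and Il6 and Cxcl2 have their highest with 25HC then PAM3.

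Among the other large rises were the natural killer receptor gene Klra2, from 0 to 4996 bp, and Cd55b, a complement regulator, from 0 to 4424 bp (adjusted p = 0.0306 and 0.031). The mitotic kinesin gene Kif4 rose by 3.15, the growth factor gene Nrg3 by 2.89, the adenylate cyclase gene Adcy2 by 2.85 and Pttg1ip2 by 3.51 on the log2 scale (adjusted p = 0.031 to 0.0445). Among the other large falls were the lectin gene Clec1a with a log2 change of −3.07, Il18r1, a cytokine receptor subunit, with −3.04, Gpr34, a lysophospholipid receptor, with −3.00, Ppp1r1c with −2.86 and Dusp27 with −2.72 (adjusted p = 0.0176 to 0.045). Ms4a13, the angiogenin-family gene Ang5 and Fem1al had 3873, 3595 and 2793 bp in untreated cells and 0 with PAM3 (adjusted p = 0.0331, 0.0271 and 0.032). With the mouse as a block the calls of Klra2, Cd55b, Kif4, Nrg3, Adcy2, Pttg1ip2, Il18r1, Gpr34, Ms4a13, Ang5 and Fem1al ended, with adjusted p from 0.0505 for Ang5 to 0.0858 for Pttg1ip2.

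In the list of inflammatory effectors and NF-κB feedback genes 7 of 41 measured members rose, 0 fell (limma) and 34 did not pass. When adjusted over the list alone, 10 rose and 0 fell. Its median log2 change was 0.21 (camera adjusted p = 0.000157, or adjusted p = 0.123 with an estimated correlation), and with only peaks of −log10 q of at least 5 the adjusted p was 0.102. Among the members were Lcn2 and Acod1, the itaconate-producing enzyme (log2 1.09, adjusted p = 0.0428, or 0.0841 with the mouse as a block). Of 30 measured cytokine and chemokine genes only the monocyte chemokine gene Ccl7 rose (log2 1.01, adjusted p = 0.0361, or 0.0737 with the block), with 3 rising when adjusted over the list alone (camera adjusted p = 0.182). Tnf had a log2 change of 0.50 (adjusted p = 0.0517), Il6 0.50 (adjusted p = 0.293), Il12b −0.53 (adjusted p = 0.318), and Il1b −0.12 (adjusted p = 0.886). Values were −0.24 for Cxcl1 (adjusted p = 0.717), 0.36 for Il10 (adjusted p = 0.224), −0.23 for Nos2 (adjusted p = 0.832) and 1.33 for Ptgs2 (adjusted p = 0.274). In other lists, Hif1a, the hypoxia regulator, rose by 0.80 (adjusted p = 0.0291, or 0.0652 with the block), and E2f8, a cell cycle repressor, rose by 0.53 (adjusted p = 0.041, or 0.0763). Ciita fell by 1.91, Cd163 by 0.75 and Clec9a by 1.40 (adjusted p = 0.0284, 0.038 and 0.04, or 0.0634, 0.0589 and 0.0645 with the block). Elane, the neutrophil elastase gene, fell by 1.31 and Kmo, an enzyme of tryptophan breakdown, by 0.74 (adjusted p = 0.0474 and 0.0475, or 0.0793 and 0.0876 with the block). The lymphocyte adhesion gene Cd2 went from 1419 bp to 0 (adjusted p = 0.0327, or 0.0683 with the block) and the lung surfactant gene Sftpc, whose window overlaps that of Bmp1, from 0 to 1148 bp (adjusted p = 0.0209, or 0.0501). None of the 36 interferon-stimulated, 25 cholesterol synthesis, 22 LXR target or 27 integrated stress response genes measured passed (limma; camera adjusted p = 0.344, 0.787, 0.709 and 0.777). Adjusted over the list alone, 2 LXR targets rose and 2 fell, and 0 passed in the other 3 lists (limma). Of 12 alternative activation genes 1 fell, or 5 when adjusted over the list alone (camera adjusted p = 0.182). On that basis 2 identity genes rose and 1 fell, 1 proliferation gene rose and 1 fell, 2 lymphocyte markers fell, and 1 dendritic cell marker rose and 3 fell. Cholesterol genes had values of 0.03 for the exporter gene Abca1 and 1.31 for Ch25h, which makes 25HC (adjusted p = 0.966 and 0.53). The fixed genes Abcg1, Srebf1, Insig1, Trib3, Chac1, Atf3, Ifit1, Arg1 and Csf1r had values from −0.65 for Chac1 to 0.74 for Ifit1 and adjusted p from 0.13 for Insig1 to 0.733 for Atf3. Ch25h had no peak in untreated A, Chac1 none in PAM3 B and Ifit1 none in untreated B. A single library thus sets much of each of these values.

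Of the 39 genes that the rule named in this comparison and that passed, 10 passed with the mouse as a block and in every fit without 1 library: Adgre1, Bmp1, Drosha, Fpr1, Fpr2, Lcn2, Nhs, Saa2, Siglech and Zfp811. The number passing was 14 without untreated A, 14 without untreated B, 26 without PAM3 A, 16 without PAM3 B, 19 and 20 without 25HC A or B, and 23 and 24 without 25HC then PAM3 A or B. With the block, 17 of the 39 passed. Drosha was at 0 in both PAM3 libraries alone, and leaving out 1 of them left the group at 0. The fits without 1 library therefore cannot test Drosha for peaks missing from lists. The count of all genes was 168 with the block (85 rising, 83 falling), 160 without untreated A (132 rising), 283 without untreated B (223 rising), 872 without PAM3 A (322 rising) and 272 without PAM3 B (76 rising). It was 185 without 25HC A, 188 without 25HC B, 304 without 25HC then PAM3 A and 314 without 25HC then PAM3 B. It was 0 (limma, 1237 at unadjusted p under 0.05) with only peaks of −log10 q of at least 5, 322 without median subtraction, 280 with the same number of peaks and 266 (167 rising, 99 falling) with the same covered length in each library.

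By region, 6050 bins of 1 kb were gained and 8111 lost with PAM3. Of the gained bins 7.67% lay within 1 kb of a gene end and 54.6% elsewhere inside a gene, and of the lost bins 10.8% and 50.9%, against 16.3% and 51.4% of all called bins. The longest gained run lay 36037 bp from Acsl1, a fatty acid activating enzyme (chromosome 8, 46430001 to 46435000), where peaks covered 233 and 0 bp in untreated cells and 4479 and 4558 bp with PAM3. Others lay in Wwox (chromosome 8, 115308001 to 115313000) and in Plekhm1, a lysosome fusion factor (chromosome 11, 103369001 to 103374000). The longest lost run lay in Cask and Gpr34 (chromosome X, 13633001 to 13638000), with 5000 and 4961 bp in untreated cells and 0 in both PAM3 libraries. Others lay in Ggta1 (chromosome 2, 35449001 to 35453000) and 22318 bp from Ptafr, the receptor gene for platelet-activating factor (chromosome 4, 132605001 to 132609000). The other splits of these 4 libraries into pairs gave at most 3314 such bins against 14161 for the labelled groups, and with 3 splits no share under 0.05 can be had.

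25HC then PAM3 against 25HC asks the same of macrophages given the oxysterol first. Its 4 libraries are others than those of the first comparison, but each gene's spread was estimated over all 8 for both. Acetylation again rose over Lcn2, Camp, Fpr1, Fpr2, Adgre1 and Nhs. It also rose over the cytokine and chemokine genes Cxcl2, a neutrophil attractant, Il12a, a subunit of interleukins that steer T cells, and Il6. Further rises lay over Sod2, the mitochondrial superoxide dismutase, and Ptgs2, the inducible prostaglandin synthase. It fell over Kmo, over C1qa, the complement recognition gene, and over Plk1, a mitotic kinase. The calls of Il6, Ptgs2, C1qa and Plk1 ended with the mouse as a block. Here 733 genes passed, with 398 rising and 335 falling. This balance moved to 184 and 66 without 25HC A, 80 and 28 without 25HC B, 161 and 395 without 25HC then PAM3 A, and 112 and 214 without 25HC then PAM3 B.

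Cxcl2 went from 1215 ± 196 to 6260 ± 263 bp (SD, n = 2 each), a log2 change of 1.96 with a standard error of 0.15 (adjusted p = 0.00844). Sod2 went from 1742 ± 38.9 to 5612 ± 838 bp (SD, n = 2 each; log2 1.42, adjusted p = 0.00748). Lcn2 rose by 1.36, Fpr1 by 1.14, Fpr2 by 1.80 and Adgre1 by 1.48 on the log2 scale (adjusted p = 0.00748 to 0.0106). Il12a went from 0 to 3157 ± 38.9 bp (SD, n = 2; adjusted p = 0.0137) and Ptgs2 from 0 to 3133 ± 787 bp (SD, n = 2; adjusted p = 0.0493, or 0.0565 with the block). Camp went from 0 to 2012 ± 172 bp (SD, n = 2; adjusted p = 0.0106), and Nhs and Zfp811 from 0 to 2862 and 2844 bp (adjusted p = 0.00456 and 0.00929). Omd, a matrix proteoglycan gene, went from 0 to 2955 bp (adjusted p = 0.0172). The lipid transporter gene Abca13 and Adcy2 rose by 3.54 and 3.06 (adjusted p = 0.0161 and 0.0232). Upp1, a uridine phosphorylase, and Jph4, a junction protein gene, had 0 bp in the 25HC group alone and 4090 and 3808 bp with PAM3 added (adjusted p = 0.0142 and 0.00291). Windows that went to 0 were those of the transporter gene Slc7a13 from 8048 bp, the adhesion gene Ncam2 from 5502 bp, Arpp21 from 3859 bp, Map3k7cl from 3388 bp, Fstl4 from 3085 bp, Lrrc14b from 2994 bp and Ranbp6 from 2862 bp (adjusted p = 0.00291 to 0.0217). Ncam2, Map3k7cl and Ranbp6 were at 0 in this group alone, and single libraries also lack windows that the other 7 have. Fam110b, the phospholipase gene Plb1 and the ion channel gene Asic2 had log2 changes of −3.13, −3.08 and −2.87 (adjusted p = 0.0433, 0.0146 and 0.0128, with 0.0773 for Fam110b with the block).

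Of 30 measured cytokine and chemokine genes, 4 rose, 0 fell (limma) and 26 did not pass, with 8 rising and 1 falling when adjusted over the list alone. The median log2 change was 0.61 (camera adjusted p = 1.7e-06, or adjusted p = 0.114 with an estimated correlation). Il6 rose by 1.42 and Ccl7 by 0.89 (adjusted p = 0.0279 and 0.0415, or 0.0582 and 0.0791 with the block), whereas Tnf had a value of 0.42 (adjusted p = 0.0664) and Il1b 0.53 (adjusted p = 0.355). Of 41 effector and feedback genes, 9 rose, 0 fell (limma) and 32 did not pass, with 16 rising and 2 falling when adjusted over the list alone (median 0.29, camera adjusted p = 2.87e-06, or adjusted p = 0.0743 with an estimated correlation). In the macrophage identity list 3 of 28 rose and 3 fell, with 7 and 3 when adjusted over the list alone. Cd14, the lipopolysaccharide co-receptor gene, rose by 0.92 and Cd36, a lipid scavenger receptor gene, by 0.68 (adjusted p = 0.0249 and 0.0257, or 0.0519 and 0.0565 with the block). C1qa, whose window overlaps those of C1qb and C1qc, had a log2 change of −0.93 (adjusted p = 0.0266, or 0.0587 with the block). Hif1a rose by 1.07 and Prdx1, an antioxidant NRF2 target, by 1.38 (adjusted p = 0.0131 and 0.0257, with 0.0581 for Prdx1 with the block). Among 22 LXR targets Smpdl3a rose by 0.70 and Mylip, a ubiquitin ligase gene, by 0.99 (adjusted p = 0.0276 and 0.0478, or 0.0565 and 0.0856 with the block). When adjusted over the list alone 4 rose and 3 fell, with a median of −0.20, a mean of 0.00 and a test direction downwards (camera adjusted p = 0.657). Kmo, Siglech and Plk1 had log2 changes of −1.44, −0.92 and −0.78 (adjusted p = 0.0106, 0.0313 and 0.0464), and Cd2 went from 891 bp to 0 (adjusted p = 0.0471). With the block the adjusted p of Siglech, Plk1 and Cd2 was 0.0666, 0.0717 and 0.0826. In other lists, adjusted over the list alone, 3 NRF2 genes rose, 2 alternative activation genes rose and 4 fell, 1 neutrophil marker rose and 2 fell, 1 lymphocyte marker rose and 3 fell, and 1 gene silent in macrophages rose and 1 fell. Of the 22 fixed genes 19 did not pass, Tnf and Il10 with the smallest adjusted p (0.0664 and 0.105) and Abcg1 with the largest (0.989).

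**Figure D2:**
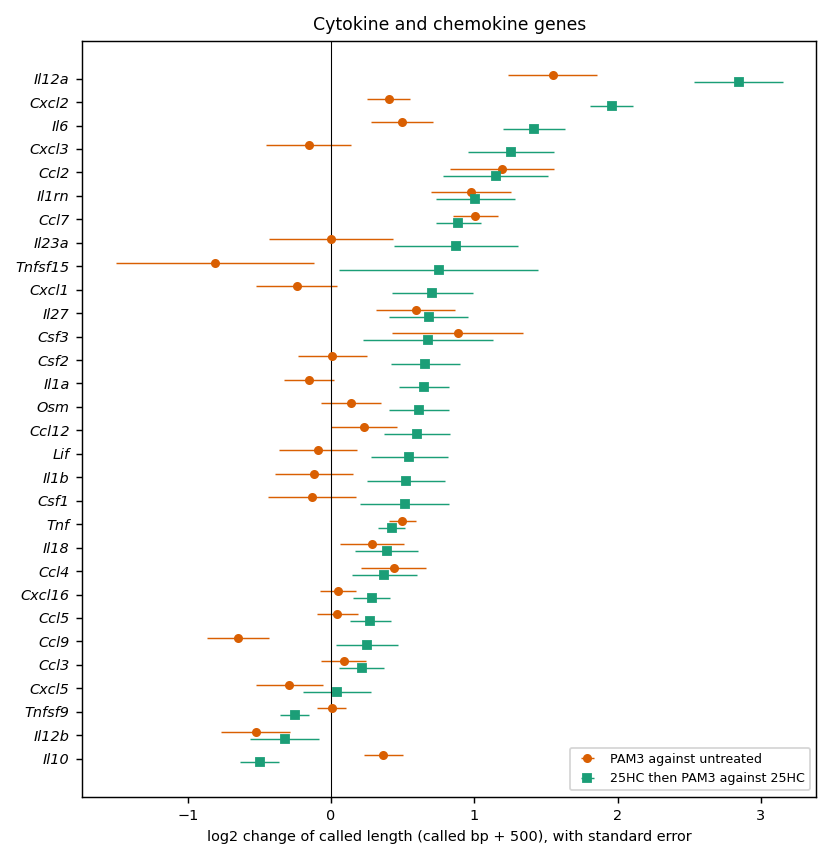
Log2 change of called length, of called bp plus 500, for each measured cytokine and chemokine gene on the horizontal axis, with standard errors, for PAM3 against untreated (circles) and for 25HC then PAM3 against 25HC (squares). The medians are 0.07 and 0.61, and the genes are ordered by the second comparison.

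Of 42 named genes that passed in this comparison, 28 passed with the block and 12 passed in every fit without 1 library as well: Adgre1, Arpp21, Cxcl2, Fpr2, Jph4, Lcn2, Lrrc14b, Map3k7cl, Nhs, Ranbp6, Sod2 and Zfp811. The number was 29 without either untreated library, 38 without either PAM3 library, 16 without 25HC A, 14 without 25HC B, 29 without 25HC then PAM3 A and 22 without 25HC then PAM3 B. The count of all genes was 281 with the block, 359 and 357 without untreated A or B, 250 without 25HC A, 108 without 25HC B and 326 without 25HC then PAM3 B. It was 1235 with 20 kb flanks, 360 without median subtraction, 390 with the same number of peaks, 462 with the same covered length and 0 (limma, 1514 at unadjusted p under 0.05) with only peaks of −log10 q of at least 5. Jph4 was at 0 in both 25HC libraries alone, and Map3k7cl and Ranbp6 in both libraries of 25HC then PAM3 alone. Leaving out 1 of those libraries left the group at 0. The fits without 1 library therefore cannot test these genes for peaks missing from lists.

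By region, 10367 bins were gained and 7474 lost. The longest gained runs lay 49609 bp from Nt5e, an enzyme that makes adenosine (chromosome 9, 88272001 to 88278000), in Clec12a, an inhibitory lectin gene (chromosome 6, 129353001 to 129358000), and 12192 bp from Picalm (chromosome 7, 90113001 to 90118000). Near Nt5e peaks covered 0 and 718 bp with 25HC, 5602 and 5291 bp with 25HC then PAM3, and 699 and 2041 bp with PAM3 alone. The longest lost runs lay in Slc7a13 (chromosome 4, 19835001 to 19839000), Maco1 (chromosome 4, 134836001 to 134840000) and Aff1 (chromosome 5, 103719001 to 103723000). Other splits of the 4 libraries gave at most 2701 bins against 17841, and again 3 splits allow no share under 0.05.

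Calls and changes with PAM3 overlapped between cells with and without 25HC. Among the rises 148 genes passed in both and among the falls 92. The calls share each gene's spread, estimated over all 8 libraries, so these counts have no plain expectation by chance. Of the 275 rises with PAM3 alone, 250 had the same sign after 25HC, and of the 287 falls, 241. Log2 changes correlated across the 14586 genes with Pearson's r of 0.455 and Spearman's rho of 0.424, though genes are not independent replicates. Of the gained bins 2103 were shared (533 if independent) and 50 had gone the opposite way, and of the lost bins 2458 were shared (515 if independent) and 114 opposite. The figures for independence count all 117757 called bins, with the 25550 called in all 8 libraries that can be neither gained nor lost. They are thus too low, and neighbouring bins are not independent.

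Averaged over cells with and without 25HC, acetylation with PAM3 was higher over Saa1 and Saa2, neighbouring acute-phase genes on chromosome 7 with overlapping windows. It was also higher over Lcn2, Fpr1, Fpr2, Camp, Acod1, Cxcl2, Il12a, Ccl7 and Sod2. It was lower over Siglech, Cd163, Kmo, the signalling adaptor gene Sla2 and the lectin gene Clec4g. In this comparison of 4 libraries with 4, 1724 genes passed, 866 rising and 858 falling. The balance moved to 565 and 371 without untreated A and to 482 and 718 without 25HC then PAM3 B.

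Saa1 had 306 ± 263 and 223 ± 40.3 bp without PAM3 and 4583 ± 1923 and 4124 ± 19.8 bp with it (SD, n = 2 each; log2 2.67, adjusted p = 0.00286), each first without and then with 25HC. Lcn2 rose by 1.33, Fpr1 by 1.15, Fpr2 by 1.81, Sod2 by 1.13 and Adgre1 by 1.90 on the log2 scale (adjusted p = 0.00261 for each). Camp and Saa2 went from 0 in all 4 libraries without PAM3 to 1612 and 3605 bp with PAM3 and to 2012 and 2690 bp with 25HC then PAM3 (adjusted p = 0.00261 for each). Nhs (adjusted p = 0.00116) and Zfp811 (adjusted p = 0.00261) likewise had peaks in the 4 libraries with PAM3 and in none without. Abca6, Sla2, Clec4g and Mrap2, an accessory protein of melanocortin receptors, were at 0 in all 4 libraries with PAM3. Without it Sla2 had 2701 and 1850 bp, Clec4g 2296 and 2105 bp and Mrap2 2435 and 1952 bp in untreated and 25HC cells (adjusted p = 0.00261, 0.0027 and 0.00276). Adcy2, Nrg3, Itgb8, an integrin gene, and Pttg1ip2 rose by 2.95, 2.71, 2.61 and 2.76 (adjusted p = 0.00603 to 0.0209), and Fer1l6 and Asic2 had log2 changes of −3.47 and −2.44 (adjusted p = 0.0277 and 0.00428). Klra2 had 0 bp in untreated cells and 4996 bp with PAM3, against 1232 bp with 25HC and 4627 bp with 25HC then PAM3 (adjusted p = 0.012). Slc7a13, Fstl4 and Arpp21 fell to 0 with 25HC then PAM3 and Ang6 to 0 with PAM3 (adjusted p = 0.0115, 0.004, 0.00319 and 0.0237).

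Of 30 cytokine and chemokine genes 7 rose and 0 fell (limma), with the same counts adjusted over the list alone (median 0.33, camera adjusted p = 0.000101, or adjusted p = 0.218 with an estimated correlation). Cxcl2 rose by 1.18, Ccl7 by 0.95, Il6 by 0.96 and Tnf by 0.46 (adjusted p = 0.0047, 0.00927, 0.0179 and 0.0141). Il12a had 368 and 0 bp in untreated and 25HC cells, and 2147 and 3157 bp with PAM3 added (adjusted p = 0.00617). Of 41 effector and feedback genes 13 rose and 1 fell, with 18 and 2 adjusted over the list alone (median 0.31, camera adjusted p = 9.68e-06, or adjusted p = 0.0798 with an estimated correlation), and Acod1 rose by 1.07 (adjusted p = 0.0103). Ptgs2 had 508 and 0 bp in untreated and 25HC cells, and 1718 and 3133 bp with PAM3 added (adjusted p = 0.0277). In the alternative activation list 0 of 12 rose (limma) and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.254). These were Cd163 with −0.64, the lectin gene Clec10a with −0.88, the lipid regulator Pparg with −0.54 and Il4ra, a cytokine receptor gene, with −0.36 (adjusted p = 0.0118, 0.0155, 0.0361 and 0.0384). Of 8 dendritic cell markers 1 rose and 3 fell, as when adjusted over the list alone (median −0.56, camera adjusted p = 0.12). Siglech had −1.76, Kmo −1.09 and Clec9a −0.96 (adjusted p = 0.00261, 0.00442 and 0.0216). Of 28 identity genes 5 rose and 2 fell, with 6 and 5 adjusted over the list alone. Tlr2, the receptor gene for PAM3, rose by 0.62, Cd14 by 0.50 and Cd36 by 0.47 (adjusted p = 0.0195, 0.0256 and 0.0144). The list's median of −0.02 and its upward test direction differ in sign (camera adjusted p = 0.891). Of 22 LXR targets 3 rose and 4 fell, with 4 and 5 adjusted over the list alone (camera adjusted p = 0.981). Smpdl3a, Mylip and Nr1h3, the LXR gene itself, rose by 0.58, 0.79 and 0.38, and Apoc1 had a log2 change of −0.51 (adjusted p = 0.0109, 0.0215, 0.0232 and 0.0295). Of 24 proliferation genes 1 rose and 2 fell, with 2 and 2 adjusted over the list alone (camera adjusted p = 0.912), Plk1 with −0.76 and Cdk1, a mitotic kinase, with −0.64 among the falls (adjusted p = 0.0122 and 0.0229).

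In the remaining lists, Hif1a rose by 0.94 and the glycolysis regulator Pfkfb3 by 0.40 (2 of 30 rose; camera adjusted p = 0.0919). Prdx1 rose by 1.01 (1 of 14 NRF2 genes; camera adjusted p = 0.343). The RNA sensor gene Ifih1 rose by 0.75 (among 2 of 36 interferon-stimulated genes that rose; camera adjusted p = 0.254). Klf6 rose by 0.52 (1 of 20 immediate-early genes; camera adjusted p = 0.891) and Ddit4 by 0.39 (1 of 27 stress response genes; camera adjusted p = 0.891). The adjusted p of these 6 genes ran from 0.00428 to 0.0484. Of 17 antigen presentation genes 2 fell, Ciita with a log2 change of −1.08 and H2-DMa with −0.32 (camera adjusted p = 0.912). Of 8 neutrophil markers Camp rose and Elane and Prtn3, whose windows overlap, fell by 1.11 and 0.42 (camera adjusted p = 0.891). Of 11 lymphocyte markers Cd2 and Cd4 fell (camera adjusted p = 0.333), with a log2 change of −0.49 for Cd4. Of 5 genes silent in macrophages Sftpc rose (camera adjusted p = 0.467). The adjusted p of these genes other than Camp ran from 0.00927 to 0.0449. Adjusted over the list alone, 1 lymphocyte marker rose and 2 fell, 2 genes silent in macrophages rose, and only 1 glycolysis and hypoxia gene and 1 interferon-stimulated gene did. None of 25 cholesterol synthesis genes, 6 fibroblast and endothelial markers, 8 erythroid and megakaryocyte markers or 15 housekeeping genes passed (limma; camera adjusted p = 0.981, 0.891, 0.981 and 0.621).

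Of 65 named genes that passed, 55 passed with the block and 36 also in every fit without 1 library, among them Lcn2, Fpr1, Fpr2, Camp, Saa1, Saa2, Adgre1, Acod1, Cxcl2, Il12a, Ccl7, Sod2, Hif1a, Prdx1, Smpdl3a, Cd163, Siglech, Kmo, Plk1 and Cd2. The number was lowest without 25HC B at 37 and highest without PAM3 A at 57. Blocked adjusted p was 0.0543, 0.0705, 0.0668, 0.0821 and 0.0691 for Pparg, Il4ra, Ifih1, Pfkfb3 and H2-DMa, 0.0551 and 0.0506 for Fer1l6 and Ang6, and 0.0628 for Prtn3. The count of all genes was 936 without untreated A, 1071 without untreated B, 887 without 25HC A, 714 without 25HC B, 1095 without median subtraction, 1122 with the same covered length and 0 (limma, 1716 at unadjusted p under 0.05) with only peaks of −log10 q of at least 5.

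In all 4 libraries with PAM3 and none of the 4 without, 2103 bins were gained, and 2458 were lost. The longest gained runs lay 21901 bp from Zfp281 (chromosome 1, 136599001 to 136603000), in the kinase gene Cdk19 (chromosome 10, 40380001 to 40384000) and in Lcn2 (chromosome 2, 32387001 to 32390000). The run in Lcn2 was covered for 2714 and 2748 bp with PAM3, 2863 and 2796 bp with 25HC then PAM3, and 0 bp in the other 4 libraries. The longest lost runs lay in St6galnac4, a sialyltransferase gene (chromosome 2, 32588001 to 32591000), in Fnip2 (chromosome 3, 79538001 to 79541000) and near Ptafr (chromosome 4, 132605001 to 132608000).

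**Figure D3:**
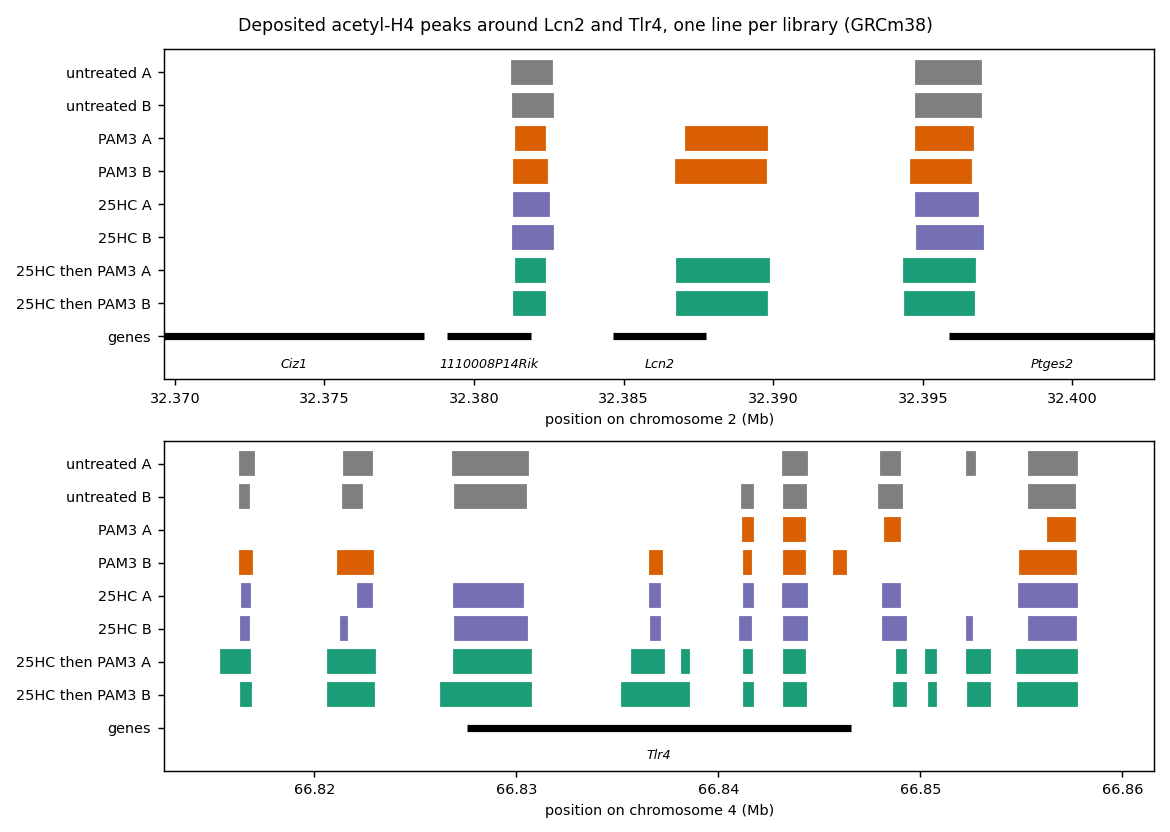
Deposited peaks around Lcn2 and Tlr4 in each of the 8 libraries, by position in Mb on chromosomes 2 and 4 of GRCm38, with gene bodies as black bars. The 4 libraries with PAM3 have a peak at the right end of Lcn2 that the others lack, and the PAM3 libraries lack the peak at the left end of Tlr4.

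25HC against untreated cells asks what the oxysterol does at rest. Few genes differed. Acetylation was called over Rab29, a small GTPase gene of the Golgi and lysosome, with 25HC and in neither untreated library. It was called in untreated cells and not with 25HC over Pycard, the inflammasome adaptor gene, Jph4 and Camkv, a kinase-like synaptic gene, and was shorter over the myosin gene Myo1h. These 5 genes passed, 1 rising and 4 falling, of 14586 tested, and none of the 5 with the mouse as a block. Rab29 (chromosome 1, 131867210 to 131872887) had 0 bp in untreated cells and 2278 ± 117 bp with 25HC (SD, n = 2; adjusted p = 0.0188). Camkv, Jph4 and Pycard had 2265 ± 201, 1743 ± 65.1 and 1606 ± 71.4 bp in untreated cells (SD, n = 2 each) and 0 with 25HC (adjusted p = 0.0372, 0.0188 and 0.0257). Myo1h went from 3056 ± 179 to 736 ± 99.7 bp (SD, n = 2 each; log2 −1.46, adjusted p = 0.0257). Rab29 was at 0 in untreated libraries alone and Camkv, Jph4 and Pycard in 25HC libraries alone, with peaks in the other 6 libraries, and the window of Pycard overlaps that of Trim72. Since libraries at 0 show almost no spread, the adjusted p of Rab29, Camkv, Jph4 and Pycard can be too small.

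No member of the 20 lists passed at rest (limma, 678 of all genes at unadjusted p under 0.05), and the smallest camera adjusted p was 0.824. Adjusted over the list alone, 1 gene silent in macrophages rose. Median log2 changes were 0.03 for LXR targets, which oxysterols activate, −0.01 for cholesterol synthesis genes, which oxysterols repress, and −0.01 for integrated stress response genes (camera adjusted p = 0.938, 0.852 and 0.824). The LXR targets Abca1, Abcg1 and Srebf1 had values of −0.22, −0.01 and 0.41, the sterol-regulated gene Insig1 0.19, and Ch25h 1.29, all at an adjusted p of 1. The value of Ch25h was 2.57 in mouse A and 0.0001 in mouse B, since untreated A had no peak there. Stress genes Trib3 and Atf3 had values of 0.02 and −0.05, and Il6 and Tnf 0.14 and 0.09, again at an adjusted p of 1. Glycolysis genes had a median of 0.03 with a downward test direction, and genes silent in macrophages a median of −0.03 with an upward one.

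With the mouse as a block 0 genes passed (limma, 646 at unadjusted p under 0.05), and the 5 named genes had blocked adjusted p of 0.14 to 0.174. The count was 52 without untreated A (48 rising, 4 falling), 97 without untreated B (92 and 5), 54 without 25HC A (3 and 51) and 1 without PAM3 A. It was 0 without PAM3 B, 25HC B or either library of 25HC then PAM3, and the 5 named genes passed in the 3 fits without untreated A, untreated B or 25HC A and in no other. It was 0 with 20 kb flanks, with a pseudocount of 2000 bp and with only peaks of −log10 q of at least 5 (limma, 846, 670 and 689 at unadjusted p under 0.05), and 9 with quantile normalisation, 12 without flanks and 15 with the same covered length. Of 1 kb bins, 1512 were gained and 3183 lost. The longest gained runs lay in Tmem171 (chromosome 13, 98691001 to 98695000), Ehbp1l1 (chromosome 19, 5724001 to 5728000) and Phf20 (chromosome 2, 156196001 to 156199000). The longest lost runs lay in the RNA-binding protein gene Stau1 (chromosome 2, 166977001 to 166980000), in the semaphorin gene Sema4a (chromosome 3, 88440001 to 88443000) and in Nxpe4 (chromosome 9, 48373001 to 48376000). Another split of these 4 libraries gave 3601 bins against 4695, and 3 splits allow no share under 0.05.

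**Figure D4:**
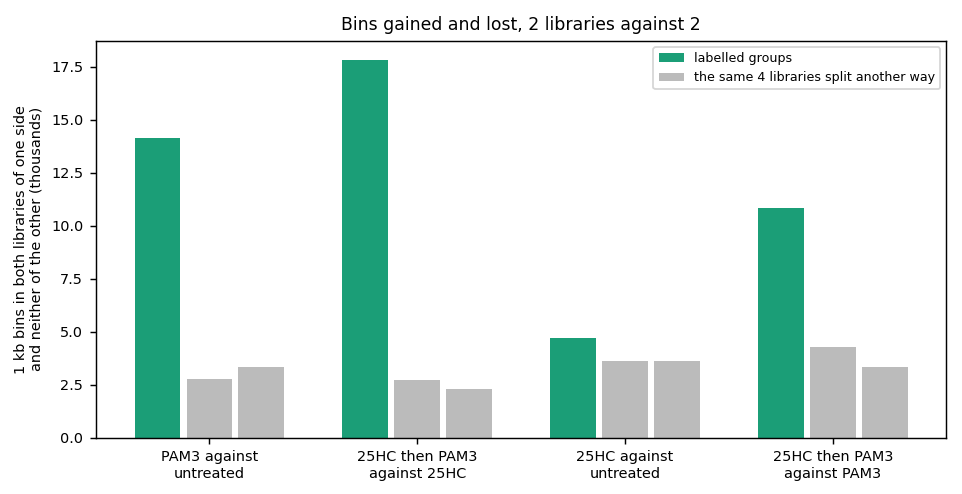
Number of 1 kb bins called in both libraries of one side and neither of the other, for the labelled groups (coloured bars) and the other splits of the same 4 libraries (grey bars). The labelled groups give 14161 and 17841 bins for PAM3 without and with 25HC, and 4695 and 10826 for 25HC without and with PAM3.

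25HC then PAM3 against PAM3 asks how the oxysterol changes acetylation in stimulated macrophages. Acetylation was longer after 25HC over the endotoxin receptor genes Tlr4 and Cd14, over the chemokine gene Cxcl2 and over Siglech, and shorter over C1qa and Kmo. Among the genes with the largest rises were Cadps, a vesicle release factor, Prrx1, a mesenchymal transcription factor, and Ltbp3, which binds latent TGF-beta. Among the largest falls were the protocadherin gene Pcdh19, the Golgi gene Golph3 and Atp6v1g3, a proton pump subunit. In all 190 genes passed, 97 rising and 93 falling, and 0 with the mouse as a block (limma). Most calls rose without either PAM3 library, and most fell without either library of 25HC then PAM3. Calls thus leaned towards shorter acetylation in the group left with a single library, whichever of its libraries was left out. The direction of the calls therefore did not hang on a particular library.

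Tlr4 went from 2604 ± 480 to 9630 ± 1444 bp (SD, n = 2 each), a log2 change of 1.70 with a standard error of 0.11 (adjusted p = 0.018), against 6197 ± 122 bp in untreated cells (SD, n = 2). Cxcl2 went from 2858 ± 161 to 6260 ± 263 bp (SD, n = 2 each; adjusted p = 0.0497). Cd14 went from 3005 ± 715 to 6007 ± 1085 bp (SD, n = 2 each; log2 0.89, adjusted p = 0.0466). Siglech rose by 1.49, and C1qa and Kmo had log2 changes of −1.07 and −1.11 (adjusted p = 0.0236, 0.0367 and 0.0342). The serotonin receptor gene Htr2b, the channel gene Kcnn3 and Prrx1 rose by 3.01, 2.93 and 2.57 (adjusted p = 0.0367, 0.0338 and 0.0208). Cadps, Omd, Ltbp3, Afap1l2, Drosha, Arhgap29 and Serpinb9b had 0 bp with PAM3 and 3818, 2955, 2891, 2444, 2339, 2175 and 2133 bp after 25HC (adjusted p = 0.0265 to 0.0462). Pcdh19, Cd55b, Morc2a, Atp6v1g3, Ncam2, Golph3, Lnx1 and Map3k7cl went from 5237, 4424, 4351, 4280, 2981, 2459, 2176 and 2011 bp to 0 (adjusted p = 0.0156 to 0.0466), and Zhx1 and Cpa5 had log2 changes of −2.98 and −2.32 (adjusted p = 0.0236 and 0.0367). Of these, Drosha and Ltbp3 were at 0 in the PAM3 group alone, and Atp6v1g3, Golph3, Ncam2 and Map3k7cl in the group with 25HC then PAM3 alone, the kind of gap that single libraries show too.

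Of 30 cytokine and chemokine genes only Cxcl2 rose, 0 fell (limma) and 29 did not pass, with 4 rising and 1 falling when adjusted over the list alone. As a list they were higher after 25HC by a median log2 of 0.46 (camera adjusted p = 2.86e-05, or adjusted p = 0.327 with an estimated correlation), by 0.28 (adjusted p = 0.0402) without PAM3 A and by 0.22 (adjusted p = 0.854) with only peaks of −log10 q of at least 5. Over 19 alternatives the adjusted p ran from 6.23e-08 to 0.854. Il6 had a value of 1.06 (adjusted p = 0.0946), Il1a 0.91 (adjusted p = 0.0866), Cxcl1 0.91 (adjusted p = 0.216), Il1b 0.45 (adjusted p = 0.518), Tnf 0.01 (adjusted p = 0.99), and the anti-inflammatory gene Il10 −0.73 (adjusted p = 0.08). None of the effector, LXR or cholesterol synthesis genes passed (limma; medians 0.11, −0.06 and −0.04, camera adjusted p = 0.376, 0.699 and 0.699), with 0.01 for Acod1, 0.18 for Abca1 and −1.27 for Ch25h (adjusted p = 0.997, 0.676 and 0.622). Ch25h had no peak in 25HC then PAM3 B, which sets much of its value. None of the 22 fixed genes passed (limma). Adjusted over the list alone, 1 stress response gene, 2 alternative activation genes and 1 erythroid and megakaryocyte marker rose, 2 dendritic cell markers rose and 2 fell, and 1 gene silent in macrophages fell. In the identity list 2 genes rose and 1 fell, or 2 and 3 when adjusted over the list alone, and Arg1, the arginase gene of alternative activation, had 0.94 (adjusted p = 0.0934).

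With the mouse as a block 0 of the 190 genes passed (limma; blocked adjusted p of 0.072 to 0.108 for the genes named here), and the count was 0 without untreated A, untreated B, 25HC A or 25HC B. It was 432 without PAM3 A (332 rising), 319 without 25HC then PAM3 A (54 rising) and 121 without 25HC then PAM3 B (22 rising). It was 91 without median subtraction, 85 with the same number of peaks, 87 with the same covered length and 0 (limma, 1342 at unadjusted p under 0.05) with only peaks of −log10 q of at least 5. Of the 26 named genes that passed, 18 did so without PAM3 A, 7 without PAM3 B, 15 without 25HC then PAM3 A and 10 without 25HC then PAM3 B.

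Of 1 kb bins 6269 were gained and 4557 lost after 25HC. The longest gained run lay in Ly75, an endocytic receptor gene of dendritic cells (chromosome 2, 60367001 to 60371000), where peaks covered 4000 and 3835 bp after 25HC then PAM3 and 0 bp in the other 6 libraries. The next lay at Tlr4 (chromosome 4, 66827001 to 66831000), with 0 bp in both PAM3 libraries, 3701 and 3704 bp after 25HC then PAM3, and 3551 and 3484 bp in untreated cells. With 25HC peaks covered 3321 and 3540 bp there, so the PAM3 libraries alone lacked this peak, a kind of gap that single lists show too. The third lay 39298 bp from the chemokine gene Cxcl5 (chromosome 5, 90716001 to 90720000). The longest lost runs lay near Gm41844 (chromosome 19, 38360001 to 38364000), in the complement regulator gene Cd55 (chromosome 1, 130428001 to 130431000) and in the kinase gene Camk1d (chromosome 2, 5294001 to 5297000). Other splits gave at most 4264 bins against 10826, with no share under 0.05 possible in 3 splits.

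The difference of the PAM3 response with and without 25HC tests whether the responses differ. No gene passed (limma, 1436 at unadjusted p under 0.05). The smallest adjusted p was 0.0734, which Tlr4 had with a difference of 1.53, higher after 25HC in both mice, as had Psmd1, a proteasome subunit gene, with 1.99. The window of Psmd1 overlaps that of Htr2b. The peak at the left end of Tlr4 was missing from both PAM3 libraries alone, a kind of gap that single lists show too. Jph4 and Pycard on the positive side and Rab29, Yars2 and Map3k7cl on the negative side had the same adjusted p, each with 1 group at 0. Il6 had a difference of 0.92 (adjusted p = 0.415), Cxcl2 1.56 (adjusted p = 0.125), Il10 −0.86 (adjusted p = 0.244) and Siglech 1.68 (adjusted p = 0.107). The cytokine and chemokine list differed by a median of 0.35 with 0 genes past the threshold (limma) and 1 rising when adjusted over the list alone (camera adjusted p = 0.00695, or adjusted p = 0.582 with an estimated correlation). Its adjusted p was 0.195 without PAM3 A, 0.0951 with the same number of peaks, 0.456 without flanks, 0.105 with the same covered length and 0.556 with only peaks of −log10 q of at least 5, in a range of 2.62e-06 to 0.582 over 19 alternatives. The median of the cytokine and chemokine list ran from 0.22 to 0.46 over the 19 alternatives. Adjusted over the list alone, 2 identity genes were positive and 3 negative, 1 dendritic cell marker was positive and 1 negative, and 1 gene silent in macrophages was negative. Without PAM3 A, 192 genes passed (175 positive), without 25HC then PAM3 A 159 (19 positive), without 25HC then PAM3 B 16 (2 positive) and without PAM3 B 1. Gene bodies without flanks gave 9, and 20 kb flanks and the same covered length gave 1 and 5.

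Averaged over cells with and without PAM3, acetylation with 25HC was higher over Tlr4 and Rab29. It was lower over Abcg8, a sterol transporter gene and LXR target, Pcdh19, Lnx1, Map3k7cl, the mitochondrial tRNA synthetase gene Yars2, Jph4 and Myo1h. Of 14586 genes 10 passed, 2 rising and 8 falling. Tlr4 had a log2 change of 0.93 with a standard error of 0.08 and Myo1h of −0.81 with 0.07, at an adjusted p of 0.0471 each. Rab29, Abcg8, Yars2, Map3k7cl and Jph4 were each at 0 in both libraries of just 1 group. Tlr4 likewise lacked the peak at its left end in both PAM3 libraries alone. Lnx1 had no peak in all 4 libraries with 25HC and 1207 ± 19.8 and 2176 ± 179 bp in untreated and PAM3 cells (SD, n = 2 each). The cytokine and chemokine list was higher with 25HC by a median of 0.27 with 0 genes past the threshold (limma; camera adjusted p = 0.000373, or adjusted p = 0.481 with an estimated correlation). Its adjusted p was 0.106 without PAM3 A and 0.978 with only peaks of −log10 q of at least 5, in a range of 2.8e-06 to 0.978 over 19 alternatives. Adjusted over the list alone, 1 LXR target fell, 2 identity genes rose and 2 fell, 1 dendritic cell marker rose and 2 fell, and 2 genes silent in macrophages rose and 1 fell. Abca1 had a value of −0.02 and Il6 0.60 (adjusted p = 0.962 and 0.212).

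The effects of 25HC without and with PAM3 shared 0 genes past the threshold and correlated across genes with Pearson's r of 0.0479 and Spearman's rho of 0.0629, genes not being independent replicates. They shared 136 gained bins (80.5 if independent, 50 opposite) and 150 lost bins (123 if independent, 114 opposite). These figures for independence are too low in the same way as those for PAM3, so no excess is read from the counts. Shared gained bins include a run in the calcium channel gene Cacnb4 (chromosome 2, 52456001 to 52458000) and bins in Fam135a and Cracdl, and shared lost ones lie in Col19a1, Fam117b and Nrp2. With the block 0 genes passed (limma; blocked adjusted p of 0.152 to 0.16 for the genes named). The count was 6 without untreated A, 1 without 25HC A, 0 without untreated B, PAM3 B or 25HC B, 240 without PAM3 A (199 rising), 169 without 25HC then PAM3 A (14 rising) and 30 without 25HC then PAM3 B (1 rising). It was 0 with a pseudocount of 2000 bp, without median subtraction, with the same number of peaks and with only peaks of −log10 q of at least 5 (limma, 1667, 1406, 1465 and 1057 at unadjusted p under 0.05), 1 with 20 kb flanks, 19 with quantile normalisation, 44 without flanks and 16 with the same covered length.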

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

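Of the tests in this part, those on the covered length of PAM3 A, on windows missing from pairs of lists, and on splits were chosen only after the results were seen.

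The cytokine and chemokine list was picked out because its response to PAM3 differed between cells with and without 25HC. The median difference over its 30 measured genes was 0.35 on the log2 scale (camera adjusted p = 0.00695, or adjusted p = 0.582 with an estimated correlation). The call ended with the same covered length in every library (adjusted p = 0.105), though the median there was 0.40 and thus no smaller. Without PAM3 A the median was 0.27. For this difference the short covered length of PAM3 A stays open, since a lost call with an undiminished median does not speak for it.

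The list also had higher values after 25HC then PAM3 than after PAM3 alone. Neighbouring loci counted more than once are argued against, since joining members within 100 kb (30 to 21) left an adjusted p of 0.000311. For this second comparison the same covered length in every library left an adjusted p of 0.000326. That setting cut the shortest peaks of the other lists and left PAM3 A, the list with the least covered length, as it was. It cannot restore peaks missing from PAM3 A, so it does not decide whether the short covered length of that library is the cause. Without PAM3 A the list's median dropped from 0.46 to 0.28. Members that vary together and a 25HC effect on cytokine loci cannot be told apart. A preset correlation raised to the estimated 0.0307 left 0.00135, but it takes the estimate as exact, and the test that estimates it from 4 residual degrees of freedom gave 0.327. Over 19 alternatives the adjusted p ran from 6.23e-08 to 0.854.

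Gene windows with at least 1000 bp called in 6 libraries and at 0 in both libraries of 1 group, among them Rab29, Pycard, Jph4, Camkv, Drosha, Map3k7cl and Yars2, numbered 36 in 4 same-group pairs of libraries and 76 in 24 pairs from different groups, 2.84 times as many per pair. The untreated pair held 2 of these windows, the PAM3 pair 12, the 25HC pair 7 and the 25HC then PAM3 pair 15. Pairs from different groups held 3.17 on average and up to 13. With at least 1500 bp the windows numbered 11 in same-group pairs and 36 in the others, 1.83 times as many per pair. True differences between groups, peaks dropped from single lists and peaks near the calling threshold cannot be told apart here. Independent drops would give a ratio near 1, and yet 651 windows were missing from just 1 library, 27 to 156 in each. The longest peaks of the windows stood at a median length percentile of 64.2 among all peaks, which decides nothing, since a single peak of the required 1000 bp already stands at 39.6 or higher. Regions missing from 1 list also lay side by side more often than unordered ones would, 121 against 21.4 neighbours in PAM3 B. Among regions with a median of at least 1500 bp, 385 were missing from same-group pairs and 608 from other pairs, 3.8 times as many per pair. By group the 385 were 45 (untreated), 79 (PAM3), 54 (25HC) and 207 (25HC then PAM3), against up to 56 in a pair from different groups.

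The mice pair the libraries, and only 18 of the 35 splits balance the mice as the labelled ones do, too few for a share under 0.05. For the average PAM3 effect, a plain fit of 4 libraries against 4 called 1290 genes in the labelled split, 1 of 35, and at most 2 in any other (0 in the others that balance the mice). For bins 1 of 35 splits reached 4561 and the highest other was 416 (356 among those that balance the mice). For the effector and feedback list 1 of 35 splits reached the p of 2.32e-08 and the smallest other was 0.00016 (0.000231 among those that balance the mice), and with an estimated correlation the list's call ended (adjusted p = 0.0798). For the cytokine and chemokine list chance cannot be excluded, since 5 of 35 splits reached the p of 4.11e-05, the smallest other being 2.56e-08 (3 of the 18, with 2.35e-07), and with an estimated correlation its adjusted p was 0.218. For the average 25HC effect it cannot be excluded for bins, where 6 of 35 splits (4 of the 18) reached 286. Nor can it for the cytokine and chemokine list, where 8 of 35 (5 of the 18) reached the p of 7.91e-05, the smallest other being 2.56e-08, although other splits also mix in the list's PAM3 effect, and with an estimated correlation its adjusted p was 0.481. For genes nothing was decided, since the labelled split called 0 (limma), a count that 35 of 35 splits reach. The highest other splits, with 1290 genes and 4561 bins, were those that part the libraries by PAM3. That points to PAM3, or the stimulation time that goes with it, as the main structure of the samples.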

How the results depend on the processing

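The alternatives without flanks and with the same covered length, and no other tests of this part, were chosen after seeing the data. Of 186 calls of named genes, 185 stayed past the threshold in the same direction without the filter, 177 with quantile normalisation, 163 with a pseudocount of 2000 bp, 144 with 20 kb flanks, 129 without median subtraction and 113 with the same number of peaks. The same covered length kept 105 of 182, gene bodies without flanks 106 of 156, and a −log10 q of at least 5 kept 0 of 167 (limma). Leaving out 1 library kept 92 and 95 (untreated A, B), 148 and 108 (PAM3), 81 and 71 (25HC), and 127 and 111 (25HC then PAM3), and 58 in all 8 fits. A group left with 1 library was assumed to vary like the others. Of 152 named values not past the threshold, 129 stayed so in all 8 fits, and 9, 5 and 2 passed with 20 kb flanks, without flanks and with the same covered length. All 8 list calls ended with an estimated correlation. A window around transcription starts was not run, since the gene table has no strand. Read depth is unknown, so what it limits was not measured. Where no cause is given below, the cause was not tested.

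With the mouse as a replicate block, 168 genes passed for PAM3 against untreated, 281 for 25HC then PAM3 against 25HC, and 0 for 25HC against untreated, for 25HC then PAM3 against PAM3 and for the average 25HC effect (limma, 646, 2110 and 1618 at unadjusted p under 0.05). It kept 100 of the 186 named calls and changed no other call than those of named genes and counts given in the report.

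For PAM3 against untreated (562 genes), counts were 322 without median subtraction, 280 with the same number of peaks, 266 with the same covered length and 0 with a −log10 q of at least 5. For 25HC then PAM3 against 25HC (733), they were 1235 with 20 kb flanks, 360, 390, 462 and 0. For 25HC against untreated (5), they were 0 with 20 kb flanks, with a pseudocount of 2000 bp and with the −log10 q minimum, 9 with quantile normalisation, 12 without flanks and 15 with the same covered length. For 25HC then PAM3 against PAM3 (190), they were 91 without median subtraction, 85 with the same number of peaks, 87 with the same covered length and 0 with the −log10 q minimum. For the difference of responses (0), they were 1 with 20 kb flanks, 9 without flanks and 5 with the same covered length. For the average PAM3 effect (1724), they were 1095 without median subtraction, 1122 with the same covered length and 0 with the −log10 q minimum. For the average 25HC effect (10), they were 1 with 20 kb flanks, 0 with a pseudocount of 2000 bp, without median subtraction, with the same number of peaks and with the −log10 q minimum, 19 with quantile normalisation, 44 without flanks and 16 with the same covered length. Counts of 0 are from limma, with 670 to 1716 genes at unadjusted p under 0.05. Leaving out 1 library gave 160 to 872, 108 to 814, 0 to 97, 0 to 432, 0 to 192, 714 to 1861 and 0 to 240 genes in these 7 comparisons.

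Log2 changes that turned sign were few. Those under the −log10 q minimum rest on a choice of peaks that may be partly at random. For PAM3 against untreated with the −log10 q minimum they were Ang5 at 0.23 and Hif1a at −0.71. For 25HC then PAM3 against 25HC with that minimum they were Slc7a13 and Map3k7cl at 0.10, Sod2 at −0.47, Cd14 at −0.0175, C1qa at 0.92 and Plk1 at 0.93, and with 20 kb flanks Cd2 at 0.0542. For 25HC then PAM3 against PAM3 with the minimum they were Prrx1 at −0.30 and Kmo at 0.96. For the average PAM3 effect with the minimum they were Tnf at −0.18, Mylip at −0.0257, Nr1h3 at −0.45, Ddit4 at −0.72, Pfkfb3 at −0.32, Cd14 at −0.60, Il4ra at 0.13 and Plk1 at 0.76, and without flanks Tnf at −0.0012, Nr1h3 at −0.0911 and Ddit4 at −0.25.

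Bins of 2 kb gave 6432, 8319, 2122 and 4896 gained and lost for PAM3 against untreated, 25HC then PAM3 against 25HC, 25HC against untreated and 25HC then PAM3 against PAM3, and 2115 and 118 for the average PAM3 and 25HC effects. Fewer bins follow from their size. Calling a bin at any overlap gave 23605, 29241, 8095, 18062, 7550 and 552, as a lower bar must. The −log10 q minimum gave 7171 bins for 25HC against untreated and 1699 for the average PAM3 effect, and it brought the difference in shared bp between same-group pairs and pairs differing in PAM3 from 0.142 to 0.0807. Leaving out 1 library gave 5292 to 7158 bins for the average PAM3 effect and 435 to 761 for the average 25HC effect, more than with 8 because fewer libraries must concur.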

Other observations

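Of the tests in this part, the one on enrichment that differs between mice was chosen only after the result was seen.

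The deposited values per peak differed between the mice of a group away from chromosome starts. Over the first 20 peaks of each chromosome the −log10 p correlated between mice with a median Spearman's rho of 0.734 across peaks, against 0.112 over the last 20, while peak lengths correlated by 0.810 and 0.799. The 0.734 argues only against enrichment that truly differs between mice all along the chromosomes, which would lower the correlation at both ends. It is part of the observed pattern, so it cannot decide on differences confined to places away from chromosome starts. Values displaced from their peaks further along each chromosome are consistent with the 0.112 and remain a candidate explanation. Over all matched peaks the median rho was 0.136 for −log10 p and 0.787 for length. Alternatives that choose peaks by these values, the minimum −log10 q and the same number of peaks, may therefore remove peaks partly at random. Their counts, list values and changes of sign thus do not decide whether strong peaks changed.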
